A study of Drosophila melanogaster with 54 samples.

How the data were processed

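RNA was sequenced from whole male fruit flies (Drosophila melanogaster) of 6 strains, each reared at 18, 25 and 29 °C and collected at 10 days of age. In 5 strains the flies carried FLucDM-GFP, a misfolding-prone firefly luciferase fused to green fluorescent protein, directed mainly to the cytoplasm (Cyto, 1 copy), the nucleus (NLS, 1 or 2 copies) or the mitochondria (Mito, 1 or 2 copies). The other strain was w1118, the isogenic control without the transgene. Per the labels, total RNA was extracted with TRIzol and libraries were made with a TruSeq RNA v2 kit. The labels name the genome builds BDGP6 and dm6. The aligner, the counting program and the read depth are not given in the sources used here.

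The deposited table gives TPM values, computed by the authors, for 13926 gene symbols in 54 libraries, and every library sums to the same total. TPM keeps no read counts, so the depth of each library is unknown and no counting interval was computed. Of the symbols, 12783 matched a gene of the BDGP6 annotation, 1095 matched 1 synonym and 48 matched neither, 5 of the latter being calendar dates. There were 71 genes at 0 in every library. Positions on BDGP6 were found for 11459 (91.3%) of the genes tested. The table holds no entry for the transgene.

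Libraries were grouped by strain and temperature into 18 groups of 3. Genes with at least 1 TPM in at least 3 libraries were kept, which left 12555. A linear model with 1 mean per group was fitted to log2(TPM + 1) of all 54 libraries with limma 3.58.1 in R 4.3.3 (moderated test with an intensity trend, 36 residual degrees of freedom, two-sided), and p-values were adjusted by Benjamini-Hochberg within each comparison at 0.05. With 1 added to each TPM, log2 fold changes of genes with few TPM are understated. Comparisons of strains are the mean of the differences at the 3 temperatures, 9 libraries against 9. Rearing temperature was compared in w1118 alone, 3 against 3, and a further contrast asked whether the difference of each strain from w1118 itself changed between 18 and 29 °C. This makes 16 comparisons. The labels number the replicates but do not say whether they were separate cultures or animals, so the p-values measure the spread between these libraries. Replicate numbers did not pair libraries: in 1 of 31 pairs of groups were the residuals of libraries with the same number correlated above 0.1 for every number.

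For gene groups, 38 lists were tested in each comparison with limma's camera, which compares a list with all other genes, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison, and again with a correlation estimated from the residuals. They include inducible heat-shock genes, mitochondrial chaperones and proteases, endoplasmic reticulum folding and degradation genes, and proteasome subunits. The lists, the comparisons and the alternatives, except where said otherwise, were chosen before the data were examined. A member of a list is said to have risen or fallen when it passed the threshold over all genes tested. Where a count adjusted over the list alone is not given beside it, the count was the same. Median log2 fold changes are over all measured members of a list. RNA came from whole flies. A rise or fall in a list of organ genes therefore cannot be told apart from a changed share of that organ.

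Named genes follow a rule fixed with the comparisons. It takes w in every group. For each strain against w1118, and for temperature in w1118, it takes the 6 genes with the largest rise and the 6 with the largest fall that passed the threshold, had the same sign at all 3 temperatures (for temperature in w1118, no overlap between the libraries of the 2 groups), reached a mean of 5 TPM on either side and had a named symbol. For the other comparisons it takes 4 and 4. It adds 2 to 4 members with the smallest adjusted p of each list that passed and of the 4 stress lists, and the 5 largest shared rises and falls of the 5 strains.

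Alternatives were a pseudocount of 0.1, no filter on low values, quantile normalization, median-ratio size factors, replicate number as a block, only the libraries of the strains compared, leaving out each library in turn, and each temperature alone. Restricting the genes tested to those on or off chromosome 2 was chosen after seeing the data. Simulated data had 50 genes changed by each of 0.25, 0.5, 1 and 2 (log2) and all other genes unchanged. More genes changed in the real data, so recovery there may differ. In the simulated data a comparison with w1118 recovered 84% of changes of 0.25 and 98% of changes of 0.5. The temperature comparison in w1118 recovered 28% and 90%, and the contrasts of strain differences between temperatures 8% and 60%. Genes that share near-identical sequence, such as the trypsins of chromosome 2, LysB, LysD and LysE, the Hsp70 copies, the Ste:CG genes and the Jonah proteases, and genes that overlap, such as p24-2 and Unc-115b, may have exchanged reads, and how such reads were assigned is not given in the sources used here.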

Results

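The data are transcript levels of whole 10-day-old males from 6 fly strains reared at 3 temperatures, with 3 libraries in each of the 18 groups. Between 11995 and 12158 genes reached 1 TPM in each library, and the 10 most abundant genes held 9.38% to 13.9% of all TPM. Within a group, libraries correlated across genes with Pearson r of at least 0.990, and between groups with r of at most 0.994 (genes are not independent replicates). The read depth behind each value is unknown.

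The gene w (white, chromosome X, 2790599 to 2796466, build BDGP6), an eye pigment transporter whose w1118 allele names the control, served as a check of the labels. It was lowest in w1118, at 2.60 ± 1.25 TPM (SD, n = 9), and ranged from 5.58 ± 1.37 TPM in NLS 1 copy to 8.24 ± 1.73 TPM in Mito 2 copies (SD, n = 9 each). Cyto held 6.90 ± 1.23, Mito 1 copy 6.48 ± 0.845 and NLS 2 copies 6.65 ± 1.57 TPM (SD, n = 9 each). All 5 differences from w1118 passed the test, with adjusted p = 4.08e-18 for Mito 2 copies and 1.67e-12 for NLS 1 copy. With 2 copies instead of 1, w rose by 0.29 on the log2 scale in the Mito strain (adjusted p = 0.00598) and did not pass in the NLS strain (0.22, adjusted p = 0.0516). At 1 copy each, NLS differed from Cyto by a similar amount (log2 -0.28, adjusted p = 0.0117). The gene w therefore sets w1118 apart from the other strains but does not check the copy labels. In w1118 it went from 1.36 TPM at 18 °C to 4.05 TPM at 29 °C (n = 3 each, log2 1.11, adjusted p = 3.93e-08), and its interaction with temperature was negative in all 5 strains (log2 -1.29 to -0.74). Over all temperatures single libraries overlap, reaching 4.39 TPM in w1118 and down to 3.67 TPM in NLS 1 copy, and within each temperature w1118 libraries lie below all others.

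**Figure D1:**
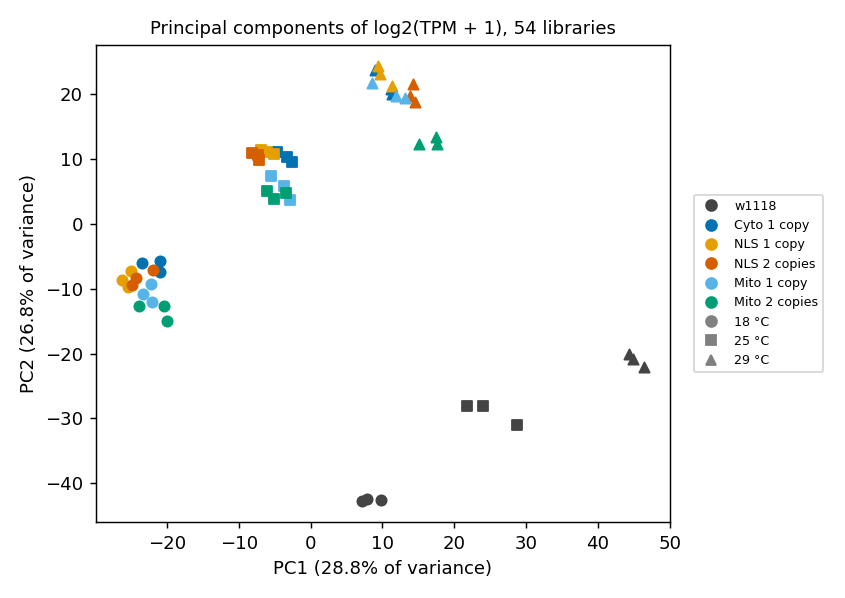
Principal components of log2(TPM + 1), with each point a library, colour the strain and shape the rearing temperature; the axes give the percent of variance (28.8% and 26.8%). The 9 w1118 libraries lie at PC2 of -20.1 or below and all libraries of the 5 transgenic strains at -15.0 or above, and the mean PC1 of each strain rises with temperature.

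The first question is what sets flies that carry the misfolding-prone protein apart from the control. Among the genes below, tobi, epsilonTry and Cyp4p2 were at 0.5 TPM or less in every w1118 library. A genetic background that w1118 does not share may explain them, as weighed later. The gene tobi (3R, 25344761 to 25346921), a target of insulin signalling that encodes an alpha-glucosidase, stood at 0.300 ± 0.0943 TPM in w1118 and at 352 ± 112 TPM in Cyto (SD, n = 9 each). Its log2 rise ran from 7.46 in both Mito strains to 8.27 in NLS 2 copies. Digestive trypsins of a cluster on 2R changed in opposite directions. The gene epsilonTry (11345237 to 11346066) was listed at 0 in w1118 and at 149 to 204 TPM in the 5 strains, and betaTry (11346325 to 11347395) went from 51.7 ± 12.2 TPM to between 2350.0 and 3070.0 TPM. Their neighbour gammaTry (11349061 to 11349870) went from 607 ± 120 TPM to between 8.20 and 13.4 TPM, log2 -6.21 to -5.51. Other shared rises were lambdaTry (log2 6.44 to 6.90) and Cyp4p2 (2R, 9237512 to 9239831), a cytochrome P450, which went from 0.134 ± 0.0696 TPM to 45.1 ± 13.2 TPM in Cyto and 126 ± 58.8 TPM in NLS 2 copies. Other shared falls were deltaTry (log2 -4.30 to -2.48), the immune-induced peptide gene IM23 (log2 -4.16 to -3.45), the cuticle gene TwdlP (3R, 26620608 to 26621364, log2 -3.66 to -3.18) and PGRP-SC1a (2R, 8709733 to 8710320), a secreted peptidoglycan-degrading enzyme of the gut (log2 -5.32 to -1.65).

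Of the 12555 genes tested, 1595 were higher and 2383 lower in all 5 strains, where independent lists of the same sizes would share 16.2 and 92.5. The 5 comparisons use the same w1118 libraries. Log2 differences of any 2 strains correlated across genes with r from 0.818 to 0.941, and with r from 0.804 to 0.925 when each strain was set against different w1118 libraries, against 0.446 to 0.543 in simulated data without strain differences.

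Hsp22 (3L, 9372931 to 9374964), a small heat-shock protein of mitochondria, rose in every strain. Its log2 rise over w1118 was 2.26 in Cyto (adjusted p = 3.67e-18), 1.63 in NLS 1 copy (9.75e-14) and 1.85 in NLS 2 copies (2.73e-15). It was 2.19 in Mito 1 copy (1.34e-17) and 2.39 in Mito 2 copies (7.09e-19), each with a standard error of 0.138. At 25 °C it stood at 32.4 ± 3.91 TPM in w1118 and at 296 ± 89.8 TPM in Cyto (SD, n = 3). At 29 °C it stood at 77.1 ± 4.31 TPM in w1118, 693 ± 235 TPM in Cyto and 739 ± 104 TPM in Mito 2 copies (SD, n = 3). Hsp67Bc, another small heat-shock protein, fell in every strain, by 0.66 in Cyto and 1.21 in NLS 2 copies on the log2 scale, and the cochaperone DnaJ-1 fell by 0.23 in Cyto and 0.32 in NLS 1 copy. Of 15 measured inducible heat-shock genes, 3 rose, 8 fell and 4 did not pass in Cyto, and the list as a whole passed its test in none of the 5 strains (adjusted p from 0.155 to 0.851). In Cyto the list had a median of -0.14, a mean of 0.02 and a downward test.

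**Figure D2:**
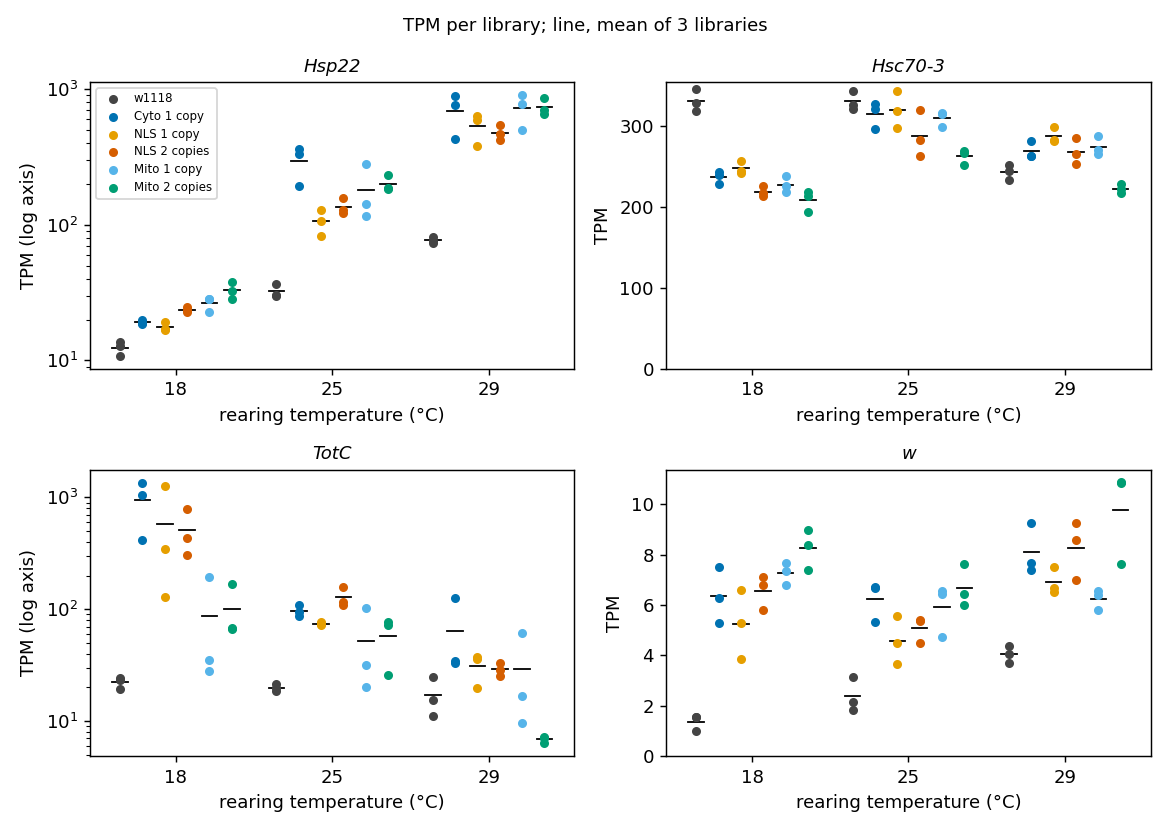
TPM of Hsp22, Hsc70-3, TotC and w in each library (points) by rearing temperature and strain (colour), with the mean of 3 libraries as a line; Hsp22 and TotC are on log axes. Hsp22 reached 739 TPM in Mito 2 copies against 77.1 TPM in w1118 at 29 °C, and TotC reached 941 TPM in Cyto against 22.2 TPM in w1118 at 18 °C.

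In Cyto flies, genes of the cytochrome P450, glycolysis and tricarboxylic acid cycle lists rose. The nuclear-encoded respiratory chain did not pass (28 up, 29 down, 28 and 30 adjusted over the list alone, adjusted p = 0.936). It had 31 up and 13 down at 18 °C, 6 and 37 at 25 °C, and 25 and 15 at 29 °C. Cyp6d2 rose by 2.03 and Cyp6a13 by 1.54 (log2), and of 77 cytochrome P450 genes 53 rose, 11 fell and 13 did not pass (53 and 12 adjusted over the list alone, median 0.23, adjusted p = 2.74e-07, adjusted p = 0.318 with an estimated correlation). In glycolysis 11 of 13 rose and none fell, among them Ald (0.48), PyK (0.36) and Eno (0.32), with adjusted p = 8.67e-05 and adjusted p = 0.432 with an estimated correlation. In the tricarboxylic acid cycle 14 of 15 rose and none fell, such as Nc73EF (0.64) and Acon (0.60), with adjusted p = 8.67e-05 and adjusted p = 0.449 with an estimated correlation. The mitochondrial genome's own transcripts rose in 10 of 13, with mt:ND1 at 0.76 and mt:CoI at 0.64, and in 8 with quantile normalization (adjusted p = 0.000275, adjusted p = 0.432 with an estimated correlation). Antioxidant genes rose in 15 of 20, fell in 1 and did not pass in 4, with the extracellular superoxide dismutase Sod3 at 0.98 (adjusted p = 0.000113, adjusted p = 0.318 with an estimated correlation).

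Genes of the ATF4 pathway, which answers amino acid and mitochondrial stress, also rose in Cyto, 12 of 16 with 2 falling and 2 not passing (median 0.26, adjusted p = 0.00598, adjusted p = 0.432 with an estimated correlation). They include crc, the fly ATF4 (0.24), and the translation inhibitor Thor (0.46). Of 16 lipid synthesis and storage genes 13 rose and 2 fell (14 and 2 adjusted over the list alone), with the lipoprotein apolpp at 0.62 (adjusted p = 0.000208, adjusted p = 0.432 with an estimated correlation). Antimicrobial peptides fell in 10 of 22 and rose in none, for example IM2 (-0.89) and CecA2 (-2.49), with a median of -0.73 (adjusted p = 0.0252, adjusted p = 0.707 with an estimated correlation). Testis genes fell in 28 of 33 and rose in 1, with the sperm protamine ProtA at -0.55 and Mst84Db rising by 1.84 against the list (adjusted p = 2.37e-05, adjusted p = 0.544 with an estimated correlation). Endoplasmic reticulum (ER) folding and degradation genes were mixed, 6 up, 13 down and 3 not passing of 22 (7 and 14 adjusted over the list alone, adjusted p = 0.24), with Der-1 at 0.45 and CaBP1 at -0.44. Mitochondrial chaperones and proteases, 4 up, 8 down and 4 not passing of 16, had adjusted p = 0.646, with a median of -0.06, a mean of 0.07 and a downward test. Proteasome subunits, 6 up, 9 down and 17 not passing of 32 (6 and 8 adjusted over the list alone), had adjusted p = 0.936, with a median of -0.01, an upward test, and a median of 0.04 with 15 up and 5 down with quantile normalization. Over all genes, 8339 of 12555 changed in Cyto, 3909 higher and 4430 lower, 373 of them at least 2-fold. More genes were lower at 18 °C (2149 higher, 3356 lower) and more were higher at 25 °C (2799 and 2380).

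In flies with 1 copy of the nuclear form, photoreceptor and lipid genes rose and testis genes fell. The blue-light opsin Rh5 (2L, 12008153 to 12009832) rose by 2.73 and the ultraviolet opsin Rh3 by 0.91, and of 20 photoreceptor genes 14 rose, 2 fell and 4 did not pass (median 0.26, adjusted p = 0.001, adjusted p = 0.573 with an estimated correlation). The photoreceptor rise was not particular to this form. That list also passed against w1118 in Cyto (13 up, 1 down, median 0.21) and Mito 1 copy (14 up, 2 down, median 0.23). Eye pigment genes passed upward in the same 3 strains. Of 33 testis genes 31 fell and 1 rose, ProtA falling by 0.66 (median -0.47, adjusted p = 2.49e-08, adjusted p = 0.485 with an estimated correlation). Cytosolic ribosomal protein genes rose in 57 of 87 and fell in 7 (58 and 9 adjusted over the list alone, median 0.10, adjusted p = 0.000159, adjusted p = 0.742 with an estimated correlation), RpL27 at 0.26 and RpL37b at -0.96. Of the cytochrome P450 genes 50 rose and 11 fell (51 and 11 adjusted over the list alone, median 0.23, adjusted p = 6.46e-08, adjusted p = 0.375 with an estimated correlation). Lipid genes rose in 14 of 16 and fell in 1. Glycolysis genes rose in 12 of 13 and fell in 1. Both lists had adjusted p = 0.000122 and adjusted p = 0.421 with an estimated correlation.

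None of the 4 stress lists passed in NLS 1 copy. Of the heat-shock genes 1 rose, 9 fell and 5 did not pass (adjusted p = 0.155). Of the mitochondrial chaperones 2 rose, 11 fell and 3 did not pass (adjusted p = 0.186), with the nucleotide exchange factor Roe1 falling by 0.59. Of the ER genes 6 rose, 13 fell and 3 did not pass (adjusted p = 0.34). Of the proteasome subunits 9 rose, 11 fell and 12 did not pass (adjusted p = 0.859), with a median of -0.02 and an upward test, where quantile normalization gave 17 up and 1 down. In all, 8643 genes changed, 3834 higher and 4809 lower, 353 at least 2-fold. The larger side depends on scaling, since 44.4% were higher as reported, 52.5% with quantile and 53.02% with median-ratio scaling.

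With 2 copies of the nuclear form, ER folding genes fell and transcripts of the mitochondrial genome, respiratory chain and muscle genes rose against w1118. Mitochondrial import genes fell in 13 of 17 and rose in 1 (median -0.17, or -0.11 with either other scaling, adjusted p = 0.0399, adjusted p = 0.566 with an estimated correlation). The ER chaperone Gp93 fell by 0.47, the disulfide isomerase ERp60 by 0.36 and CaBP1 by 0.62 (log2), and of 22 ER genes 1 rose, 15 fell and 6 did not pass (median -0.14, or -0.08 with median-ratio scaling, adjusted p = 0.006, adjusted p = 0.498 with an estimated correlation). The mitochondrial transcript mt:ND1 rose by 1.15, and 10 of 13 transcripts of the mitochondrial genome rose and none fell (median 0.46, or 0.22 with quantile normalization, adjusted p = 1.13e-05, adjusted p = 0.498 with an estimated correlation). Nuclear genes of the respiratory chain rose in 45 of 86 and fell in 16 (median 0.08, adjusted p = 0.00768, adjusted p = 0.685 with an estimated correlation), and the median was 0.14 with median-ratio scaling. This turned with temperature, with 61 rising and 14 falling at 18 °C and 6 rising and 27 falling at 29 °C. Muscle contractile genes rose in 14 of 24 and fell in 3, with TpnC4 at 0.92 (adjusted p = 0.00607, adjusted p = 0.589 with an estimated correlation), and at 29 °C 3 rose and 10 fell. Lipid genes rose in 12 of 16 and none fell (median 0.33, adjusted p = 1.13e-05, adjusted p = 0.498 with an estimated correlation). Testis genes fell in 29 of 33 and rose in 1 (1 and 30 adjusted over the list alone, adjusted p = 4.69e-06, adjusted p = 0.566 with an estimated correlation). Heat-shock genes (2 up, 8 down, 5 not passing, adjusted p = 0.457, with 1 up and 8 down at 18 °C and 6 up and 4 down at 29 °C) and mitochondrial chaperones (1 up, 10 down, 5 not passing, adjusted p = 0.237) did not pass. Neither did proteasome subunits (9 up, 7 down, 16 not passing, 9 and 6 adjusted over the list alone, adjusted p = 0.219, upward with adjusted p = 0.0327 under quantile normalization). In all, 8425 genes changed, 3282 higher and 5143 lower, 359 at least 2-fold. The larger number of falls depends on scaling, since 39.0% of changed genes were higher as reported and 49.7% and 50.3% with quantile and median-ratio scaling.

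In flies with 1 copy of the mitochondrial form, genes of the tricarboxylic acid cycle and respiratory chain and transcripts of the mitochondrial genome rose. All 15 genes of the tricarboxylic acid cycle rose, such as Acon (0.44) and Nc73EF (0.41), with a median of 0.23 (adjusted p = 6.31e-06, adjusted p = 0.416 with an estimated correlation). Respiratory chain genes rose in 47 of 86 and fell in 16, ND-SGDH at 0.36 and Cyt-c1 at 0.36 (median 0.09, adjusted p = 0.00288, adjusted p = 0.646 with an estimated correlation). Transcripts of the mitochondrial genome rose in 10 of 13, with mt:ND1 at 0.98 (median 0.45, or 0.26 with quantile normalization, adjusted p = 2.67e-05, adjusted p = 0.416 with an estimated correlation). The tricarboxylic acid cycle and mitochondrial genome lists were not particular to this form. In NLS 1 copy they passed with 14 and 10 rising and none falling (medians 0.13 and 0.36). There the mitochondrial genome list did not pass with quantile normalization (adjusted p = 0.0611). Tricarboxylic acid cycle genes also passed in NLS 2 copies (8 up, none down). Neither list passed between Mito and Cyto or Mito and NLS at 1 copy. Testis genes fell in 29 of 33 and rose in 1 (adjusted p = 2.67e-05, adjusted p = 0.633 with an estimated correlation). Of the cytochrome P450 genes 41 rose and 12 fell (adjusted p = 6.31e-06, adjusted p = 0.416 with an estimated correlation). Heat-shock genes (2 up, 8 down, 5 not passing, 2 and 9 adjusted over the list alone, adjusted p = 0.475) and mitochondrial chaperones (4 up, 10 down, 2 not passing, adjusted p = 0.626, median -0.09, mean 0.06 and a downward test) did not pass. Neither did ER genes (3 up, 15 down, 4 not passing, adjusted p = 0.0517) or proteasome subunits (3 up, 11 down, 18 not passing, 3 and 10 adjusted over the list alone, adjusted p = 0.526, and 10 up and 5 down with quantile normalization). In all, 7939 genes changed, 3337 higher and 4602 lower, 337 at least 2-fold. Of these 42.0% were higher as reported, 49.02% with quantile and 49.3% with median-ratio scaling, and at 25 °C more were higher (2547) than lower (1926).

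Flies with 2 copies of the mitochondrial form had more respiratory chain and muscle transcripts and transcripts of the mitochondrial genome than w1118 and fewer of ER genes. Of 86 nuclear-encoded respiratory chain genes 62 rose, 9 fell and 15 did not pass (63 and 11 adjusted over the list alone, median 0.16, adjusted p = 1.74e-11, adjusted p = 0.334 with an estimated correlation), with ND-SGDH at 0.45 and Cyt-c1 at 0.41. Tricarboxylic acid cycle genes rose in 14 of 15 and none fell (median 0.25, adjusted p = 2.5e-08, adjusted p = 0.334 with an estimated correlation). In addition 10 of 13 mitochondrial transcripts rose and none fell (median 0.57, or 0.28 with quantile normalization, adjusted p = 1.88e-07, adjusted p = 0.334 with an estimated correlation). Muscle genes rose in 15 of 24 and fell in 1 (16 and 1 adjusted over the list alone), the flight-muscle troponin TpnC4 by 1.07 (adjusted p = 3.86e-05, adjusted p = 0.531 with an estimated correlation). These are averages over temperatures, and at 29 °C the respiratory chain had 5 rising and 17 falling (median -0.04), the tricarboxylic acid cycle 2 and 3, muscle genes 3 and 5 and mitochondrial transcripts 7 and none. ER genes fell in 16 of 22, rose in 2 and did not pass in 4 (2 and 17 adjusted over the list alone, median -0.25, adjusted p = 3.86e-05, adjusted p = 0.334 with an estimated correlation), with Gp93 at -0.59, ERp60 at -0.43 and CaBP1 at -0.70.

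The seminal fluid gene Sfp24Ba (2L, 3667977 to 3668551) went from 127 ± 40.0 TPM in w1118 to 13.3 ± 10.4 TPM in Mito 2 copies (SD, n = 9 each, log2 -3.48). The Stellate copy Ste:CG33239 (X, 14056895 to 14057618) went from 15.1 ± 5.57 TPM to being listed at 0. Heat-shock genes (2 up, 7 down, 6 not passing, adjusted p = 0.851) and mitochondrial chaperones (4 up, 5 down, 7 not passing, adjusted p = 0.764, median -0.03, mean 0.12 and an upward test, and 4 up and 3 down with median 0.02 with median-ratio scaling) did not pass. Neither did proteasome subunits (2 up, 3 down, 27 not passing, adjusted p = 0.86, median -0.02 and an upward test, and 5 up and 3 down with quantile normalization) in this strain. In all, 7017 genes changed, 2458 higher and 4559 lower, 325 at least 2-fold. Of the changed genes 35.03% were higher as reported, against 48.3% and 49.4% with quantile and median-ratio scaling.

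**Figure D3:**
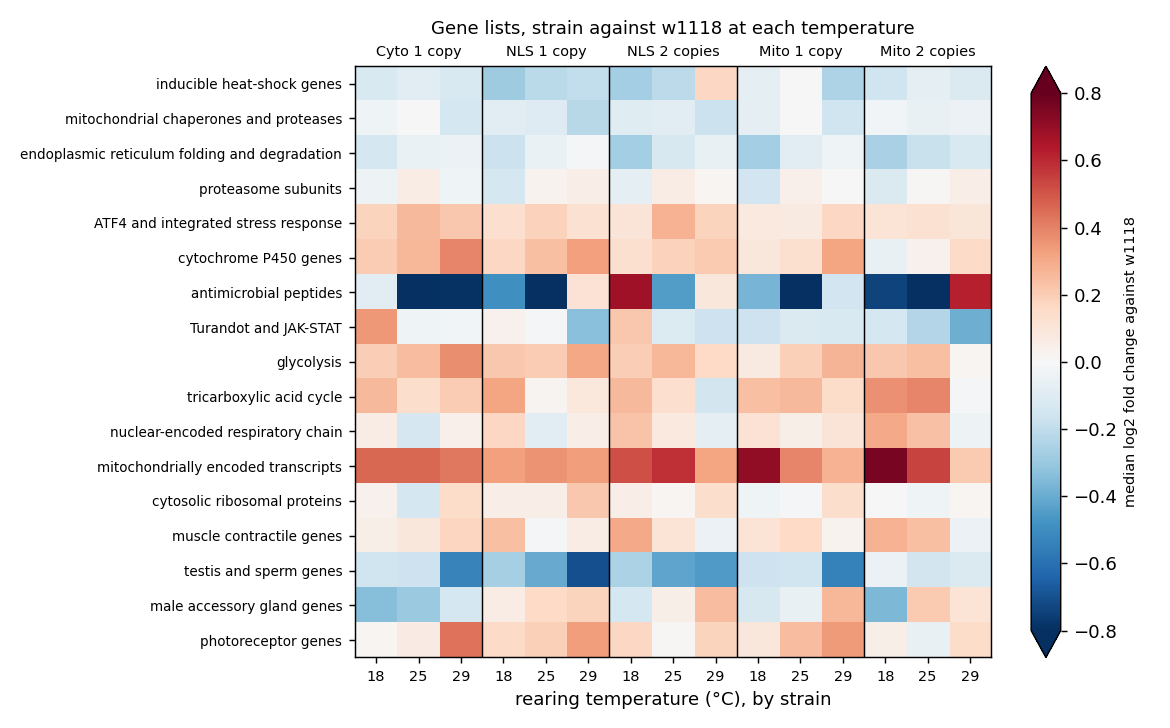
Median log2 fold change against w1118 of 17 gene lists (vertical) in each strain at each rearing temperature in °C (horizontal), red for higher and blue for lower. Respiratory chain genes of Mito 2 copies go from 0.30 at 18 °C to -0.04 at 29 °C, and proteasome subunits of NLS 1 copy from -0.14 to 0.05.

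The next question is how strains with 2 transgene copies differ from those with 1. Between NLS flies with 2 copies and 1 copy, ER and photoreceptor genes fell and testis genes rose. The cytochrome P450 genes Cyp6w1 (2R, 6173684 to 6176195) and Cyp6d2 (2R, 22652573 to 22654530) stood at 7.29 ± 1.51 and 10.2 ± 1.495 TPM with 2 copies. With 1 copy they stood at 37.6 ± 3.13 and 41.7 ± 12.4 TPM (SD, n = 9 each, log2 -2.23 and -1.88). Sfp24Ba fell by 2.87 (adjusted p = 5.91e-28) and PGRP-SC1a by 3.16 (5.74e-17), while phu (3R, 9494801 to 9496723) rose by 2.03 (4.78e-08), as did Cyp4p2 by 1.24 (1.28e-23). ER genes fell in 13 of 22 and none rose, with Der-1, a channel of ER-associated degradation, at -0.48 and CaBP1 at -0.22 (median -0.09, adjusted p = 4.48e-05, adjusted p = 0.761 with an estimated correlation). Photoreceptor genes fell in 9 of 20 and rose in 1 (1 and 11 adjusted over the list alone, adjusted p = 0.000553, adjusted p = 0.761 with an estimated correlation), with the opsin Rh4 at -0.59. Testis genes rose in 8 of 33 (11 adjusted over the list alone, adjusted p = 0.00388, adjusted p = 0.761 with an estimated correlation), ProtB by 0.34. Heat-shock genes (3 up, none down, 12 not passing, adjusted p = 0.12) and mitochondrial chaperones (2 up, none down, 14 not passing, adjusted p = 0.538, median -0.00, mean 0.03 and an upward test) did not pass. Neither did proteasome subunits (6 up, none down, 26 not passing, adjusted p = 0.0993). In all 3534 genes changed, 1606 higher and 1928 lower, 48 at least 2-fold, and at 29 °C more were higher (1339) than lower (1026). As reported 45.4% were higher, against 49.4% with median-ratio scaling and 50.9% without NLS 1 copy 29 °C replicate 2.

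Between Mito flies with 2 copies and 1 copy, respiratory chain and testis genes rose and ER and photoreceptor genes fell. Of 33 testis genes 29 rose and none fell, ProtB by 0.46 (median 0.18, adjusted p = 1.56e-09, adjusted p = 0.615 with an estimated correlation). Of 86 respiratory chain genes 47 rose and 2 fell (49 and 2 adjusted over the list alone, median 0.09, adjusted p = 3.13e-07, adjusted p = 0.615 with an estimated correlation), while at 29 °C 15 rose and 43 fell. ER genes fell in 14 of 22 and rose in 2, Der-1 at -0.55 (median -0.10, adjusted p = 0.00153, adjusted p = 0.615 with an estimated correlation). Photoreceptor genes fell in 15 of 20 and rose in 1, Rh4 at -0.56 (adjusted p = 0.000288, adjusted p = 0.69 with an estimated correlation). Antioxidant genes fell in 12 of 20 and rose in 2 (2 and 14 adjusted over the list alone, adjusted p = 0.0039, adjusted p = 0.615 with an estimated correlation). Genes named in the NLS strain changed here too, with Cyp4p2 up by 1.16, Sfp24Ba at -3.03, PGRP-SC1a at -2.94, Cyp6w1 at -2.06 and Cyp6d2 at -1.92. The photolyase phr (2R, 7825289 to 7827319) went from 21.7 ± 1.78 to 39.4 ± 1.66 TPM (SD, n = 9 each). Hsp22 did not pass (0.20, adjusted p = 0.239). Heat-shock genes (2 up, none down, 13 not passing, 1 up adjusted over the list alone, adjusted p = 0.574) and mitochondrial chaperones (5 up, 2 down, 9 not passing, adjusted p = 0.0622) did not pass. Neither did proteasome subunits (6 up, 1 down, 25 not passing, 3 and 1 adjusted over the list alone, adjusted p = 0.184, and 3 up and 4 down with quantile normalization). In all 5295 genes changed, 2367 higher and 2928 lower, 39 at least 2-fold. The larger side depends on scaling (44.7% higher as reported, 50.7% with quantile and 53.1% with median-ratio scaling) and on temperature (502 higher and 1907 lower at 25 °C, 2980 and 2208 at 29 °C).

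Both copy comparisons moved many genes alike. In both, 1031 genes were higher and 1371 lower, where independent lists would share 302.8 and 450, and 42 genes went opposite ways (r = 0.774 across genes). Of 150 placed genes that changed the same way by at least 0.5 (log2) in both, 133 (88.7%) lie on chromosome 2, which holds 39.8% of the tested genes with a position. Genes of chromosome 2 showed such a change in 2.92% and other genes in 0.246%. Der-1, CaBP1 and ProtB lie on 2L. List tests off chromosome 2, with the preset correlation, were chosen after seeing the data. There 8 of 14 ER genes fell in NLS and none rose, and 9 fell and 2 rose in Mito (adjusted p = 0.0015 and 0.0208). Testis genes rose in 5 and 20 of 24 and none fell (adjusted p = 0.0015 and 5.58e-09). Eye pigment genes lost their call in both strains (0.193 and 0.504). A test of whether the NLS and Mito copy comparisons differ called 297 genes, 83 higher and 214 lower in Mito, 1 of them at least 2-fold.

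The comparison of compartments sets strains with 1 copy each against each other, without w1118. NLS flies had more transcripts of male accessory gland and ribosomal protein genes than Cyto flies. Of 22 accessory gland genes, which make seminal fluid, 20 rose and 2 fell, Acp76A by 1.02 and Acp26Aa by 0.66 (median 0.34, adjusted p = 5.91e-18, adjusted p = 0.161 with an estimated correlation). Of 87 ribosomal protein genes 47 rose and 4 fell, RpS13 by 0.16 (52 and 4 adjusted over the list alone, median 0.09, adjusted p = 5.35e-15, adjusted p = 0.928 with an estimated correlation). Testis genes fell in 27 of 33 and none rose (0 and 28 adjusted over the list alone, median -0.17, adjusted p = 1.65e-06, adjusted p = 0.928 with an estimated correlation), can at -0.45. The receptor gene mthl6 (3L, 7485967 to 7487918) stood at 5.24 ± 2.13 TPM in NLS and 0.216 ± 0.0935 TPM in Cyto (SD, n = 9 each, log2 2.29). The Y-linked phosphatase gene Pp1-Y1 (Y, 9833 to 10786) was listed at 0 in NLS and at 5.41 ± 1.01 TPM in Cyto.

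Hsp22 was lower in NLS than in Cyto (log2 -0.63, adjusted p = 0.000454), as were Hsp83 (-0.17, adjusted p = 5.29e-05) and the storage protein Lsp2 (-1.77, adjusted p = 4.36e-07). Heat-shock genes (1 up, 9 down, 5 not passing, adjusted p = 0.0609) and mitochondrial chaperones (none up, 8 down, 8 not passing, 9 down adjusted over the list alone, adjusted p = 0.0609) did not pass. Neither did ER genes (1 up, 3 down, 18 not passing, 1 and 2 adjusted over the list alone, adjusted p = 0.53, median 0.01, mean -0.00 and an upward test, and 5 up and 1 down with quantile normalization) or proteasome subunits (2 up, 2 down, 28 not passing, 1 and 0 adjusted over the list alone, adjusted p = 0.649). In all 4034 genes changed, 1194 higher and 2840 lower, 62 at least 2-fold, although at 18 °C more were higher (1295) than lower (844). Of the changed genes 29.6% were higher as reported, 48.2% with quantile and 49.6% with median-ratio scaling.

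Mito flies had more respiratory chain and accessory gland transcripts than Cyto flies and fewer of the Turandot stress peptides. Of 86 respiratory chain genes 40 rose and 3 fell, ATPsynG by 0.31 and ND-B14.5B by 0.34 (42 and 3 adjusted over the list alone, median 0.08, adjusted p = 2.71e-11, adjusted p = 0.326 with an estimated correlation). Accessory gland genes rose in 16 of 22 and none fell (18 adjusted over the list alone, median 0.25, adjusted p = 4.15e-12, adjusted p = 0.32 with an estimated correlation). Among Turandot and JAK-STAT genes 7 of 11 fell and none rose (8 adjusted over the list alone, median -0.24, adjusted p = 0.000213, adjusted p = 0.167 with an estimated correlation). TotX stood at -1.48 and TotC (3R, 20872988 to 20873580) was at 55.8 ± 59.7 TPM in Mito and 368 ± 493 TPM in Cyto (SD, n = 9 each, log2 -2.10, adjusted p = 2.64e-05). Lipid genes fell in 11 of 16 and none rose, Lsd-2 at -0.24 (adjusted p = 0.000209, adjusted p = 0.451 with an estimated correlation). Fat body genes fell in 9 of 13 and rose in 1 (2 and 9 adjusted over the list alone, adjusted p = 0.00613, adjusted p = 0.326 with an estimated correlation), with the storage protein Lsp2 at -1.62, while at 29 °C 1 rose and none fell. Heat-shock genes (1 up, 3 down, 11 not passing, adjusted p = 0.801, median 0.00, mean -0.06 and a downward test) and mitochondrial chaperones (none up, 2 down, 14 not passing, 0 down adjusted over the list alone, adjusted p = 0.921) did not pass. Neither did ER genes (none up, 5 down, 17 not passing, 4 down adjusted over the list alone, adjusted p = 0.126) or proteasome subunits (none up, 6 down, 26 not passing, 5 down adjusted over the list alone, adjusted p = 0.125). In all 3320 genes changed, 1216 higher and 2104 lower, 47 at least 2-fold. Of the changed genes 36.6% were higher as reported and 47.3% with either other scaling.

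Mito flies had more testis, mitochondrial import and chaperone transcripts than NLS flies and fewer of lipid and ribosomal protein genes. Testis genes rose in 29 of 33 and none fell (30 adjusted over the list alone, median 0.17, adjusted p = 1.92e-09, adjusted p = 0.586 with an estimated correlation). Import genes rose in 8 of 17 and none fell, Tim17b by 0.15 (9 adjusted over the list alone, adjusted p = 0.00245, adjusted p = 0.524 with an estimated correlation). Hsp22 rose by 0.55 (adjusted p = 0.00203) and Hsp27 by 0.17, and of 15 heat-shock genes 6 rose and none fell (median 0.10, adjusted p = 0.0434, adjusted p = 0.602 with an estimated correlation and 0.0624 with quantile normalization). Mitochondrial chaperones rose in 6 of 16 and none fell, l(2)tid by 0.17 (adjusted p = 0.0321, adjusted p = 0.702 with an estimated correlation and 0.111 with quantile normalization). Lipid genes fell in 11 of 16 and none rose (13 adjusted over the list alone, adjusted p = 5.32e-07, adjusted p = 0.524 with an estimated correlation). Ribosomal protein genes fell in 29 of 87 and rose in 3 (adjusted p = 3.9e-07, adjusted p = 0.634 with an estimated correlation).

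ER genes (none up, 5 down, 17 not passing, Xbp1 at -0.15) and proteasome subunits (none up, 5 down, 27 not passing, 3 down adjusted over the list alone) were lower in Mito than in NLS, with 7 and 11 down with quantile normalization. Their tests gave adjusted p = 0.0259 and 0.0321 (adjusted p = 0.634 and 0.707 with an estimated correlation). The GTPase gene RabX2 (X, 10417429 to 10418219) went from 1.91 ± 0.450 TPM in NLS to 6.52 ± 1.27 TPM in Mito (SD, n = 9 each, log2 1.37). The receptor gene mthl8 (3L, 22428 to 26308) went from 18.1 ± 3.07 to 7.01 ± 1.504 TPM (SD, n = 9 each, log2 -1.26). In all 3900 genes changed, 2415 higher and 1485 lower, 23 at least 2-fold, although at 18 °C more were lower (1240) than higher (661). Of these 61.9% were higher as reported, 50.8% with quantile and 49.98% with median-ratio scaling.

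**Figure D4:**
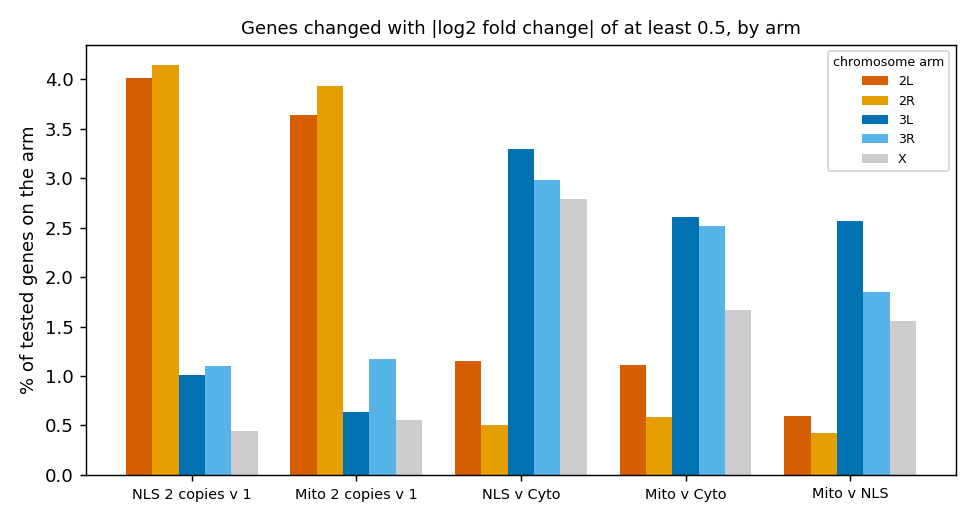
Percent of the tested genes on each chromosome arm (bars, colour for the arm) that changed by at least 0.5 on the log2 scale, in 5 comparisons between transgenic strains (horizontal). Arms 2L and 2R hold 4.01% and 4.14% in the NLS copy comparison against 1.01% and 1.10% on 3L and 3R, while in NLS against Cyto 3L and 3R hold 3.30% and 2.98%.

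Rearing at 29 instead of 18 °C was compared in w1118 alone, 1 strain without the transgene. Glycolysis, respiratory chain, muscle and accessory gland transcripts fell and ribosomal, proteasome and mitochondrial chaperone transcripts rose. Accessory gland genes fell in 19 of 22 and rose in 1, Acp33A at -1.68 (median -0.86, adjusted p = 2.25e-09, adjusted p = 0.632 with an estimated correlation). Glycolysis genes fell in 10 of 13 and none rose, Gapdh1 at -1.24 and Pgk at -1.06 (median -0.53, adjusted p = 6.98e-07, adjusted p = 0.632 with an estimated correlation). Respiratory chain genes fell in 52 of 86 and rose in 12, ATPsynbeta at -1.02 (median -0.21). Muscle genes fell in 14 of 24 and rose in 2, Mf at -1.53 (median -0.40). Both lists had adjusted p = 4.51e-06 and adjusted p = 0.632 with an estimated correlation. Ribosomal protein genes rose in 55 of 87 and fell in 4 (56 and 4 adjusted over the list alone, median 0.20, adjusted p = 1.29e-06, adjusted p = 0.754 with an estimated correlation). Mitochondrial chaperones rose in 13 of 16 and none fell, Hsp22 by 2.54 and CG11267, the fly Hsp10, by 0.52 (7 rising with quantile normalization, adjusted p = 0.00146, adjusted p = 0.632 with an estimated correlation). Proteasome subunits rose in 19 of 32 and fell in 1, Rpn8 by 0.40 (adjusted p = 0.00214, adjusted p = 0.754 with an estimated correlation and 0.444 with quantile normalization, where 9 rose and 4 fell).

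In w1118 at 29 °C the cytosolic chaperones Hsp83 (-1.07) and DnaJ-1 (-0.94) fell while Hsp23 rose by 0.80, and the heat-shock list, 3 up, 6 down and 6 not passing of 15, did not pass (adjusted p = 0.397, median -0.15, mean 0.01 and a downward test). ER genes, 8 up, 11 down and 3 not passing, did not pass either (adjusted p = 0.3), while the ER chaperone Hsc70-3 (X, 11801696 to 11807117), the fly BiP, fell by 0.44 (adjusted p = 1.5e-08). Large single changes were the chitin deacetylase Cda9 (2R, 17128480 to 17130334), at 19.5 ± 0.866 TPM against 0.380 ± 0.162 (log2 3.90), and the storage protein Lsp1beta (2L, 898500 to 901316) at 40.0 ± 14.8 against 2.27 TPM (log2 3.61). Falls included the moulting hormone gene ETH (2R, 24794670 to 24795482) at 1.61 ± 0.846 against 16.6 ± 1.86 TPM (log2 -2.80) and the seminal fluid gene Sfp78E (3L, 21683098 to 21684042) at 18.1 ± 1.02 against 118 ± 5.82 TPM (SD, n = 3 each, log2 -2.63). In all 7040 genes changed, 3633 higher and 3407 lower (51.6% higher, and 49.2% with quantile normalization), 474 at least 2-fold.

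The last question is whether the difference of each strain from w1118 depends on rearing temperature. For ER folding genes it did so in all 5 strains, and in none of them with an estimated correlation. The median of the ER list against w1118 went from -0.14 at 18 °C to -0.04 at 29 °C in Cyto and from -0.26 to -0.12 in Mito 2 copies. The interaction was positive for Hsc70-3, at 0.62 in Cyto, 0.65 in NLS 1 copy, 0.73 in NLS 2 copies, 0.71 in Mito 1 copy and 0.54 in Mito 2 copies (log2, adjusted p from 5.53e-09 in NLS 2 copies to 3.62e-06 in Mito 2 copies). Its level in w1118 was 330.3 ± 14.2 TPM at 18 °C and 243 ± 8.97 TPM at 29 °C, and in Mito 2 copies 208 ± 12.7 and 222 ± 5.49 TPM (SD, n = 3). The ER list had 10, 9, 9, 11 and 10 of 22 members with a positive interaction in Cyto, NLS 1 copy, NLS 2 copies, Mito 1 copy (12 adjusted over the list alone) and Mito 2 copies. None had a negative one, while median-ratio scaling gave 6 positive and 2 negative in Cyto, with a median of 0.08, and a median of 0.10 in NLS 2 copies. Quantile normalization gave a median of 0.16 in NLS 1 copy. Its medians as reported were 0.16, 0.11, 0.15, 0.16 and 0.13, with adjusted p = 0.0256, 4.59e-05, 5.56e-05, 8.81e-06 and 2.76e-05. In the same order it had adjusted p = 0.661, 0.552, 0.305, 0.33 and 0.186 with an estimated correlation.

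Proteasome subunits showed the same direction in 4 strains. In NLS 1 copy 19 of 32 subunits had a positive interaction and none a negative one (20 adjusted over the list alone, median 0.20, adjusted p = 9.99e-10, adjusted p = 0.552 with an estimated correlation), Prosbeta4 at 0.48. In Mito 1 copy 17 did (21 adjusted over the list alone, median 0.17, adjusted p = 8.81e-06, adjusted p = 0.559 with an estimated correlation). In Mito 2 copies it was 12 (18 adjusted over the list alone, median 0.16, adjusted p = 1.74e-07, adjusted p = 0.24 with an estimated correlation) and in NLS 2 copies 5 (4 adjusted over the list alone, median 0.11, adjusted p = 0.00539, adjusted p = 0.687 with an estimated correlation). These counts depend on scaling, with 28 in NLS 1 copy, 28 in Mito 1 copy (median 0.26), 10 in Mito 2 copies and 16 in NLS 2 copies with quantile normalization. With median-ratio scaling they were 19, 14, 8 and 1, and the median in NLS 2 copies was 0.20 with quantile and 0.06 with median-ratio scaling. In Cyto 1 did (0 adjusted over the list alone, median 0.03, adjusted p = 0.954), and there the list passed with quantile normalization (adjusted p = 0.000677) and its median was -0.06 with median-ratio scaling. At 18 °C none of the 32 subunits rose and 19 fell in NLS 1 copy, 20 fell in Mito 1 copy and 17 in Mito 2 copies against w1118. In NLS 2 copies 8 fell and none rose, and in Cyto 7 fell and 2 rose.

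Respiratory chain genes had negative interactions in all 5 strains, and with an estimated correlation in Mito 2 copies alone. In the strains with 1 copy their median against w1118 was lowest at 25 °C. At 18, 25 and 29 °C it was 0.06, -0.13 and 0.04 in Cyto. It was 0.17, -0.09 and 0.06 in NLS and 0.12, 0.04 and 0.10 in Mito. Whether the interaction differs between 1 and 2 copies was not tested. Respiratory chain genes of Mito 2 copies had a median of 0.30 against w1118 at 18 °C, with 67 of 86 rising, and of -0.04 at 29 °C, with 5 rising and 17 falling. The interaction was negative in 62 of 86 and positive in 1 (1 and 65 adjusted over the list alone, median -0.32, adjusted p = 7.44e-30), ATPsynO at -0.61. This was the only list result of the 16 comparisons that passed with an estimated correlation (adjusted p = 0.0355). The adjustment covers the 38 lists of this comparison and not all 608 list tests, so a single call may arise by chance. In NLS 2 copies it was negative in 48 and positive in 1 (2 and 61 adjusted over the list alone, median -0.27, or -0.17 with quantile normalization, adjusted p = 1.35e-17, adjusted p = 0.17 with an estimated correlation). The strains with 1 copy had medians of -0.07 in Cyto, with 2 up and 18 down (1 and 16 adjusted over the list alone). They were -0.12 in NLS, with 0 and 19, and -0.05 in Mito, with 1 and 14 (1 and 10 adjusted over the list alone). The tests gave adjusted p = 0.00533, 0.000283 and 0.0343 in Cyto, NLS and Mito. With an estimated correlation these were adjusted p = 0.785, 0.567 and 0.834, and with quantile normalization 0.531, 0.113 and 0.287. In Cyto quantile normalization gave 9 up and 7 down, with a median of -0.01, and in NLS 1 copy the median was -0.06. With median-ratio scaling the median was -0.16 in Cyto and -0.09 in Mito 1 copy. Muscle genes had a negative interaction in 17 of 24 in NLS 2 copies (19 adjusted over the list alone, median -0.38, adjusted p = 2.52e-13, adjusted p = 0.17 with an estimated correlation), Mf at -0.96. In Mito 2 copies it was negative in 14 and positive in 1 (2 and 17 adjusted over the list alone, median -0.28, adjusted p = 2.98e-11, adjusted p = 0.133 with an estimated correlation). The muscle list did not pass in Cyto (9 up, 3 down, median 0.18, adjusted p = 0.184, and 0.00954 with quantile normalization), NLS 1 copy (0.103) or Mito 1 copy (0.113).

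In Mito 2 copies the interaction was also negative in 13 of 15 tricarboxylic acid cycle genes and positive in none (1 and 13 adjusted over the list alone, median -0.47, adjusted p = 2.17e-13, adjusted p = 0.133 with an estimated correlation). This list passed in NLS 2 copies (10 negative, 11 adjusted over the list alone, median -0.35, or -0.23 with quantile normalization, adjusted p = 4.05e-07, adjusted p = 0.407 with an estimated correlation) and NLS 1 copy (8 negative, median -0.28, or -0.11 with quantile normalization, adjusted p = 7.12e-05, adjusted p = 0.567 with an estimated correlation). It passed in Cyto (1 up, 7 down, median -0.13, adjusted p = 0.0205, adjusted p = 0.785 with an estimated correlation and 0.42 with quantile normalization) and did not in Mito 1 copy (adjusted p = 0.212). Transcripts of the mitochondrial genome had a negative interaction in 7 of 13 in Mito 2 copies (1 up and 9 down adjusted over the list alone, median -0.58, or -0.43 with quantile normalization, adjusted p = 4.45e-07, adjusted p = 0.158 with an estimated correlation). In Mito 1 copy 7 were negative and 1 positive (median -0.37, adjusted p = 0.00501, adjusted p = 0.612 with an estimated correlation). The list did not pass in Cyto (adjusted p = 0.954), NLS 1 copy (0.886) or NLS 2 copies (0.2, and 0.0104 with quantile normalization).

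Stress genes differed in how they depended on temperature. Hsp22 had a positive interaction in every strain, at 2.50 in Cyto (adjusted p = 4.99e-07), 2.27 in NLS 1 copy (3.55e-06), 1.73 in NLS 2 copies (0.00019), 2.14 in Mito 1 copy (1.02e-05) and 1.91 in Mito 2 copies (4.87e-05). The heat-shock list passed in NLS 2 copies, where 7 of 15 rose and none fell (8 adjusted over the list alone, median 0.32, adjusted p = 0.00194, adjusted p = 0.298 with an estimated correlation), among them Hsp83 at 0.41 and Hsp70Bc at 1.36. It did not pass in Cyto (2 up, 1 down, 12 not passing, adjusted p = 0.954) or NLS 1 copy (1, 1 and 13, adjusted p = 0.529). Nor did it in Mito 1 copy (2, 1 and 12, adjusted p = 0.714, and 2 up and 3 down with median-ratio scaling) or Mito 2 copies (3, 0 and 12, adjusted p = 0.679). Mitochondrial chaperones passed in no strain, with 2 up and 3 down in Cyto (2 and 5 adjusted over the list alone) and 2 and 7 in NLS 1 copy. There were 2 and 1 in NLS 2 copies, 3 and 4 in Mito 1 copy and 1 and 0 in Mito 2 copies (adjusted p from 0.277 to 0.942). These counts depend on scaling, with 3 up and 0 down in Cyto, 3 and 2 in NLS 1 copy, 4 and 0 in NLS 2 copies and 4 and 1 in Mito 1 copy with quantile normalization. With median-ratio scaling they were 1 and 9, 2 and 7, 1 and 5, and 3 and 6. As reported, in each strain the median of this list was negative, its mean positive and its test downward.

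Turandot peptides, which are secreted under stress and infection, were high in the cold in some strains. TotA (3R, 20871036 to 20871700) stood at 18 °C at 153 ± 26.02 TPM in w1118, 1763 ± 786 TPM in Cyto and 1265 ± 370 TPM in NLS 2 copies. At 29 °C it stood at 181 ± 51.1 TPM in w1118 and 188 ± 93.7 TPM in Cyto (SD, n = 3 each). TotC at 18 °C was 22.2 ± 2.60 TPM in w1118, 941 ± 477 TPM in Cyto and 86.4 ± 94.9 TPM in Mito 1 copy (SD, n = 3 each). The list of 11 had a negative interaction in 4 strains, Cyto (4 down, none up, median -0.45, adjusted p = 0.00597, adjusted p = 0.661 with an estimated correlation). The others were Mito 2 copies (4 down, none up, median -0.36, adjusted p = 0.00107, adjusted p = 0.133 with an estimated correlation), NLS 1 copy (5 down, 1 up, median -0.34, adjusted p = 0.0449, adjusted p = 0.567 with an estimated correlation) and NLS 2 copies (3 down, none up, 4 down adjusted over the list alone, median -0.26, adjusted p = 0.0232, adjusted p = 0.442 with an estimated correlation). It did not pass in Mito 1 copy (adjusted p = 0.681). Testis genes also had negative interactions, in 23 of 33 in Cyto (25 adjusted over the list alone, median -0.35, adjusted p = 1.87e-08, adjusted p = 0.661 with an estimated correlation). They were negative in 24 in NLS 1 copy (median -0.42, adjusted p = 9.99e-10, adjusted p = 0.567 with an estimated correlation) and in 22 in Mito 1 copy (25 adjusted over the list alone, median -0.37, adjusted p = 3.58e-09, adjusted p = 0.575 with an estimated correlation). None was positive. In NLS 2 copies 7 were negative (9 adjusted over the list alone, median -0.22, adjusted p = 0.00107, adjusted p = 0.78 with an estimated correlation), 5 with quantile and 19 with median-ratio scaling. The list did not pass in Mito 2 copies (1 up, none down, 0 up adjusted over the list alone, adjusted p = 0.187). The accessory gland gene Acp54A1 (2R, 17133445 to 17133750) fell from 1846 ± 88.6 TPM at 18 °C to 764 ± 92.1 TPM at 29 °C in w1118 and stood at 897 ± 35.6 and 2298 ± 772 TPM in NLS 2 copies (SD, n = 3 each).

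Counts of genes with an interaction were 4063 in Cyto (2251 positive, 1812 negative), 3171 in NLS 1 copy (1227 and 1944), 2503 in NLS 2 copies (1323 and 1180), 3521 in Mito 1 copy (1642 and 1879) and 1940 in Mito 2 copies (1175 and 765). All 5 strains shared 321 positive and 192 negative ones, where independent lists would share 0.284 and 0.241. All 5 use the same w1118 libraries, and with different w1118 libraries for each strain the interactions of any 2 strains correlated across genes with r from 0.418 to 0.677. The side with more genes depended on scaling in Cyto, where 55.4% were positive as reported and 35.6% with median-ratio scaling, in NLS 2 copies (52.9% and 35.8%) and in Mito 2 copies (60.6% and 48.8%). In Mito 1 copy it was 46.6%, and 50.3% without Mito 1 copy 18 °C replicate 2.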

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

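The tests of explanations for single patterns here and in the later parts were chosen after the result was seen, as were the counts restricted to genes on or off chromosome 2, while the comparisons of library assignments were chosen before. The counts, genes and lists given first are those in which a difference between strains itself differed by a test, either between 18 and 29 °C or between the NLS and Mito strains. The 3 patterns weighed after them are not tests of that kind.

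The difference between a transgenic strain and w1118 changed between 18 and 29 °C for 4063 genes in Cyto, 3171 in NLS 1 copy, 2503 in NLS 2 copies, 3521 in Mito 1 copy and 1940 in Mito 2 copies. In each strain 1 of the 100 assignments of the libraries, the real one, gave as many. Chance spread between these libraries is therefore an unlikely source. The assignments cannot speak to chance differences between cultures, since the labels do not say whether replicates were separate cultures. The highest other counts were 2161, 1773, 811, 1055 and 635. The difference between the strains with 2 copies and 1 copy was not the same in Mito and NLS for 297 genes (limma, adjusted), and 2099 genes had an unadjusted p under 0.05.

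In Cyto the interactions were 3.2 for the gut protease Jon66Ci, 3.13 for deltaTry, 2.68 for the moulting hormone ETH, 2.6 for epsilonTry, -3.56 for TotC, -3.43 for TotA, -2.58 for the maltase Mal-B1 and -2.43 for TotX (log2). In NLS 1 copy they were 4.65 for the immune gene edin, 4.2 for deltaTry, 2.84 for ETH, 2.32 for the seminal fluid gene Acp54A1, -3.22 for TotC, -2.84 for TotA and -2.76 for Mal-B1. TotM was at -2.69 in that strain and did not pass without NLS 1 copy 18 °C replicate 1 (-1.48, adjusted p = 0.143). In NLS 2 copies they were 2.86 for Jon66Ci, 2.58 for Acp54A1, 2.51 for vanin-like, 2.4 for the mannosidase LManIII, -4.04 for the antibacterial AttD, -3.67 for TotA, -3.56 for TotC and -3.19 for Mal-B1.

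In Mito 1 copy the interactions were 2.5 for the storage protein Lsp1alpha, 2.22 for ETH, 2.14 for Hsp22, -2.8 for Mal-B1, -2.06 for the gene to (takeout), and -2.01 for the cuticle gene Cpr66Cb. For att-ORFB it was 4.31, and without w1118 29 °C replicate 1 it was 3.81 and did not pass (adjusted p = 0.0536). For the Stellate copy Ste:CG33237 it was -2.13 (adjusted p = 0.0412), and this call depends on the model and on single libraries. It did not pass with replicate number as a block (adjusted p = 0.0507) or with only the strains compared (0.0622). It did not pass without Mito 1 copy 18 °C replicate 1 (-1.375, adjusted p = 0.205) or replicate 2 (-1.74, 0.128). Nor did it without replicates 1, 2 and 3 in turn of Mito 1 copy at 29 °C (-2.12, -2.14 and -2.15), of w1118 at 18 °C (-2.18, -2.14 and -2.09) or of w1118 at 29 °C (-2.08, -2.16 and -2.16). In Mito 2 copies the interactions were 2.25 for the odorant-binding gene Obp56h, 2.11 for Acp54A1, 2.1 for the gut protease Jon99Fi, -3.96 for Mal-B1, -3.14 for TotC and -2.68 for TotA. PGRP-SC1a was at -2.37 in that strain, and at -0.05 with a pseudocount of 0.1 (adjusted p = 0.98). For edin it was 4.32, and it did not pass without Mito 2 copies 18 °C replicate 1 (4.11, adjusted p = 0.0518), Mito 2 copies 29 °C replicate 1 (3.06, 0.127) or w1118 18 °C replicate 1 (3.81, 0.0758).

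In Mal-B1 both sides of the interaction moved. In w1118 it rose from 9.82 ± 2.05 TPM at 18 °C to 82.8 ± 1.61 TPM at 29 °C, and in Mito 2 copies it went from 7.10 ± 1.47 to 3.18 ± 1.25 TPM (SD, n = 3 each).

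As groups, ER folding genes had median interactions of 0.16 in Cyto, 0.11 in NLS 1 copy, 0.15 in NLS 2 copies, 0.16 in Mito 1 copy and 0.13 in Mito 2 copies. Proteasome subunits had 0.2 in NLS 1 copy, 0.11 in NLS 2 copies, 0.17 in Mito 1 copy and 0.16 in Mito 2 copies. Nuclear-encoded respiratory chain genes had -0.07 in Cyto, -0.12 in NLS 1 copy, -0.27 in NLS 2 copies, -0.05 in Mito 1 copy and -0.32 in Mito 2 copies. Heat-shock genes had 0.32 in NLS 2 copies. With an estimated correlation between genes, the respiratory chain in Mito 2 copies was the only one of these list results that passed (adjusted p = 0.0355). It is 1 call of 608 list tests, adjusted within its comparison alone, and may arise by chance. With median-ratio scaling the ER median in Cyto was 0.08, and in Cyto the respiratory chain did not pass with quantile normalization (adjusted p = 0.531), nor did it in NLS 1 copy (0.113) or Mito 1 copy (0.287).

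The first pattern weighed is that large changes between 2 copies and 1 copy were shared by the NLS and Mito strains. The share of genes with such a change was 11.85 times higher on chromosome 2 than elsewhere, while the changes with temperature in w1118 showed a ratio of 1.07. Sequence differences carried on chromosome 2 of the strains with 2 copies are a candidate explanation, and the values it needs are there. Copy number acting through the protein on genes anywhere in the genome cannot be the whole cause, since 88.67% of these changes lie on chromosome 2, which holds 39.8% of the tested genes with a position. Off chromosome 2, 904 genes moved the same way in both strains by any amount, where independent lists would share 293. Most of these changes were under 0.5 (log2) in at least 1 strain. For them copy number and the rest of the genotype cannot be told apart, because within each compartment each number of copies is a single strain.

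The second pattern is that large differences between the strains with 1 copy, named for compartments, lie mostly off chromosome 2. Genes of chromosome 2 showed such a difference at most 0.3553 times as often as other genes over the 3 comparisons, and at most 19% of the differences lie there. Sequence differences on chromosomes X, Y and 3 may explain them. The Y-linked Pp1-Y1, listed at 0 outside Cyto, may be such a case, though sequence was not examined. Compartment acting on genes anywhere in the genome cannot be the whole cause of the large differences. Whether it contributes to the smaller ones was not tested.

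The third pattern is the set of differences from w1118 shared by all 5 strains. There were 9 genes at 5 TPM or more in every library of 1 side and at 0.5 TPM or less in every library of the other, 8 of them off in w1118, while 0 genes behaved so between 18 and 29 °C over all strains and 2 did within w1118. A genetic background that w1118 does not share may explain these 9, although the labels call the control isogenic. They include tobi, epsilonTry and Cyp4p2, named above among the shared rises. Over the genes chosen for this test, differences from w1118 were as a whole not larger with 2 transgene copies than with 1. The slope of those with 2 copies on those with 1 was 0.9175 in NLS and 0.892 in Mito. It covers genes called in Cyto whose difference with 1 copy had the same sign there. Of these genes, 35.75% in NLS and 32.59% in Mito lay farther from w1118 with 2 copies. At single temperatures, over all these genes or those off chromosome 2, the slope was at most 0.947. Large differences weigh most in the slope, and choosing genes by their sign with 1 copy lowers it. Taking genes called in Cyto, itself a strain with 1 copy, also favours the 1-copy side. Spread in the 1-copy values lowers the slope further. These choices could hide a modest growth with copies. The slope cannot tell whether part of the genes respond to copies. A single aberrant w1118 library is argued against, since at least 6572 genes changed in each strain when any 1 library was left out. Carrying the transgene at all, in whatever number, stays open.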

How the results depend on the processing

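The counts restricted to genes on or off chromosome 2 were chosen after the result was seen, and the other alternatives were chosen before. With a pseudocount of 0.1, no filter, quantile normalization, median-ratio scaling, replicate number as a block, and only the strains compared, the counts of changed genes in all 16 comparisons stayed within 1.5 times, as did all 246 counts without 1 library. With 18 °C alone the counts were 5505 for Cyto and 4903 for Mito 1 copy against w1118, 1580 and 1121 for 2 copies against 1 in NLS and Mito, and 2139, 1651 and 1901 for NLS against Cyto, Mito against Cyto and Mito against NLS. With 25 °C alone they were 5179 for Cyto, 4473 for Mito 1 copy, 1256 and 2409 for the copies of NLS and Mito, and 2077 and 1534 for NLS and Mito against Cyto. With 29 °C alone they were 4277 for Mito 2 copies, 1679 and 1089 for NLS and Mito against Cyto, and 432 for Mito against NLS. These settings use fewer libraries. With fewer genes tested, off chromosome 2, 1361 and 2446 genes changed with copies in NLS and Mito. With only genes of chromosome 2, 1284, 1036 and 1325 changed for NLS against Cyto, Mito against Cyto and Mito against NLS. Of 210 list calls, 180 were kept with quantile normalization, 206 with the block and 1 with an estimated correlation. The estimated correlation is taken from the residuals of the genes, in place of the preset value. All but 1 of the list calls therefore depend on using the preset value. Of 1134 values of named genes, 83 lost their call in at least 1 alternative and 0 reversed. TPM keeps no counts, so what depth limits is unknown.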

Other observations

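The test of the slope of the differences with 2 copies on those with 1 was chosen after the result was seen, and the comparisons of library assignments were chosen before. Some gene groups belong to none of the questions above. Against w1118, the P450 genes Cyp6a14 and Cyp6a2 moved apart in NLS 2 copies, Cyp6a14 at 1.75 and Cyp6a2 at -1.69 (log2). The lactate dehydrogenase ImpL3 rose by 0.52 in Cyto and 0.56 in Mito 1 copy, and the serine synthesis gene CG11899 by 0.40 to 0.59 over the 5 strains.

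Among assignments of the libraries, 1 of 100, the real one, gave as many changed genes in each comparison between strains. Chance spread between these libraries is therefore an unlikely source of the counts. Chance differences between cultures cannot be judged this way, since it is not known whether replicates were separate cultures. The real count and the highest other were 8339 and 7460 for Cyto, 8643 and 5266 for NLS 1 copy, 8425 and 4370 for NLS 2 copies, 7939 and 5937 for Mito 1 copy and 7017 and 3731 for Mito 2 copies against w1118. For 2 copies against 1 they were 3534 and 1013 in NLS and 5295 and 4395 in Mito. Between compartments they were 4034 and 1465 for NLS against Cyto, 3320 and 677 for Mito against Cyto, and 3900 and 1305 for Mito against NLS. The highest others for Cyto against w1118 and for the copies of Mito exchange 1 library between the groups. For temperature in w1118 there are too few splits (10) for a share under 0.05, with 7040 genes in the real one and 0 in the highest other.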
